A study of Mus musculus with 8 samples.

How the data were processed

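Total RNA of 8 samples was measured on mouse Illumina bead arrays, 2 arrays in each of 4 groups. Per the labels, IEL of C57BL/6 mice were grown for 48 h on anti-CD3 at 1 µg/ml with interleukins 2, 3, 4 and 15, kept for 14 days in interleukin 2, sorted into CD8αβ and CD8αα cells, and taken at 0 h or after 24 h on anti-CD3. RNA was amplified and labelled with biotin, per the labels with an Ambion TotalPrep kit. No label states the array version, and none says whether the replicates came from separate cultures or animals.

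The deposited intensity values are average bead signals per array ID, without normalization per the file headers. The deposited bead numbers and bead standard errors go with them; a typical ID held 45 beads and its standard error was 3.52 to 3.80% of the signal. The deposited detection p-value compares each ID with the negative control beads of its array, per the file headers. The deposited log2 values are the submitters' own, made with lumi per the labels (version not given in the sources used here) and quantile-normalized between arrays. They served as an alternative only, since their low end is compressed (lowest value 7.24, median 7.45). Each array's log2 values correlated with its own intensities with r between 0.977 and 0.993. For replicate 1 of CD8αα IEL at 24 h that r was 0.980, just under its r of 0.981 with another array.

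The groups, comparisons, tests, alternatives and gene lists were chosen before the data were examined. Background was corrected by a normal and exponential model with offset 16, followed by quantile normalization and log2 (the neqc function of limma 3.58.1 in R 4.3.3). The function takes the background from detection p-values. Run first on all IDs, and with its results seen, it gave an implausibly wide background, because the detection p-value of an ID that averages several probes is not a rank of its average signal. The analysis therefore used the 22828 IDs read as single-probe (72.5%) for the background, from which 936 negative control bead types were inferred, and the version on all IDs was kept as an alternative. Median signals were 71.1 to 82.0 and background means 65.9 to 75.9.

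IDs with a detection p under 0.01 in both arrays of at least 1 group were kept, 8912 of 31492. This filter removed 642 bright IDs, 638 of which average several probes, so detection read from the signal was added as an alternative after this was seen. Symbols were updated by Entrez ID (10669 IDs) or by accession (5494), kept from the table (5401) or taken from an ID equal to a current symbol (368), and 9560 IDs stayed unnamed. The brightest ID stood for each gene, which left 7326 genes.

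A limma model with a mean per group was fitted to all 8 arrays, with 4 residual degrees of freedom, moderated variances and Benjamini-Hochberg adjustment at 0.05 within each of 5 comparisons: both responses to anti-CD3, the subsets at 0 h, the subsets at 24 h, and the difference of the responses. All adjusted p-values of genes are limma values. SE is the moderated standard error of the log2 change. Where a gene was undetected on both arrays of a group, or on 1 array of the lower group, the fold is given as "at least", from the lowest level detected on those arrays or the measured level, whichever was higher, while the log2 change beside it is the fitted value. The rule for 1 array was added after the results were seen. Detection for these folds, the receptor and CD8 genes and the markers of other cells was read from the signal through the single-probe IDs of the same array. Of 35 gene lists, 28 had 5 or more tested genes and were tested by camera in limma, with its preset correlation of 0.01 and again with a correlation estimated from the data. Counts "adjusted over the list alone" repeat the Benjamini-Hochberg step within a list. List medians with undetected members at their bound use the same lowest detected level.

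The genes named are the 6 largest rises and 6 largest falls per comparison among genes that passed and whose arrays did not overlap between groups, unnamed models passed over, with up to 3 members per list in its main direction and up to 2 in the other. The sorting genes and a fixed set of activation genes are always given. On simulated data with variances drawn from the fitted prior, the model recovered 8.96% of 2-fold, 80.6% of 4-fold and 87.9% of 8-fold changes in the CD8αβ response, 17.9%, 71.6% and 92.4% in the CD8αα response, 17.9%, 68.7% and 92.4% between the subsets at 0 h, 8.96%, 64.2% and 95.5% between them at 24 h, and 4.48%, 52.2% and 74.2% for the difference of the responses, with 4 to 6 unchanged genes called and 0 with the wrong sign. A first simulation, with noise drawn another way, had 1 call of the wrong sign and was replaced. The simulated noise was independent between arrays, whereas real arrays of the same replicate number deviated alike. Far fewer genes were changed than had an unadjusted p under 0.05 in either response, so these rates may not hold for the data.

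Alternatives were other backgrounds, scalings, detection filters and probe summaries, the submitters' log2 values, the replicate number or the chip as a block, chip 1 alone, only the arrays compared, trended and robust variances, array weights, each array left out, and camera with an estimated correlation or fry for the lists. Outlying arrays were not sought by a rule, since groups of 2 allow none. For the same reason the array weights came out equal within each group. They ran from 0.780 in CD8αα IEL at 24 h to 1.27 in CD8αβ IEL at 0 h, so that setting weighs groups and not single arrays.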

Results

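Intestinal intraepithelial lymphocytes (IEL), T cells that sit between the epithelial cells of the gut, were isolated from C57BL/6 mice, expanded in culture, sorted into 2 subsets and profiled as total RNA on Illumina bead arrays, without and with 24 h of renewed stimulation through CD3, the signalling part of the T cell receptor. Each of the 4 groups, CD8αβ IEL and CD8αα IEL at 0 h and at 24 h, held 2 arrays. No group was kept for 24 h without anti-CD3, so anti-CD3 cannot be told apart from 24 h more in culture. A response below is the change from 0 h to 24 h, whichever of these brought it about. The labels give the CD8αβ IEL an αβ receptor. They disagree on the receptor of the CD8αα IEL, with TCRcd in the titles, TCRαα in the source names and TCRγδ in the protocol and design texts, so this subset is named here by its CD8 chain. Between 7747 and 9119 of the 31492 array IDs were detected per array (24.6 to 29.0%), and the normalized values of both arrays of a group correlated across genes with r between 0.956 and 0.968. The number of arrays limits the precision. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The arrays lay on 2 chips. Chip 1 held 6 arrays, and chip 2 held only replicate 2 of CD8αα IEL at 0 h and at 24 h. Values with the chip as a block and within a chip stand beside the results. Arrays of the same replicate number also deviated alike from their group means (r from 0.493 to 0.664 over the pairs of groups). The chip block therefore cannot separate chip from replicate number, and between the subsets it takes a shared replicate shift out of CD8αα IEL only. With the replicate number as a block more genes passed within and between the subsets. Those counts stand with the alternatives.

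The receptor and CD8 genes were read first, because they define the sorted subsets. Cd8b1, the CD8β chain, stood at a log2 signal of 13.50 ± 0.12 (SD, n = 2) in CD8αβ IEL at 0 h and 13.04 ± 0.26 at 24 h, against 9.61 ± 1.15 and 9.36 ± 0.84 in CD8αα IEL. Read from the signal, it was detected on all 4 CD8αα arrays too (8.80 and 10.43 at 0 h, 8.76 and 9.95 at 24 h). By the deposited detection p it was detected there only in replicate 2. The source of this signal was not tested. The array ID TCRD-V1, a δ chain variable segment, was detected on all 4 CD8αα arrays (9.80 ± 1.01 at 0 h and 7.37 ± 0.84 at 24 h) and on none of the CD8αβ arrays (4.71 ± 0.21 and 4.70 ± 0.10). Tcra-V13.1, an α chain segment, was detected on all 4 CD8αβ arrays (7.61 ± 1.12 and 6.78 ± 0.61) and on 0 of the CD8αα arrays. Tcrb-V13, a β chain segment, was bright in every group, with means of 15.55 and 15.32 in CD8αβ IEL and 15.22 and 14.82 in CD8αα IEL at 0 h and 24 h. The IDs of Cd8a, Cd4 and Gzmb, the gene of granzyme B, were detected on 0 of the 8 arrays and give no level, and Mki67, bright on every array, was not tested because its deposited detection p was over 0.01 on each. The CD3 chains Cd3d, Cd3e, Cd3g and Cd247 passed the test in none of the 5 comparisons, though Cd3g passed as lower in the CD8αα response with the chip as a block.

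**Figure D1:**
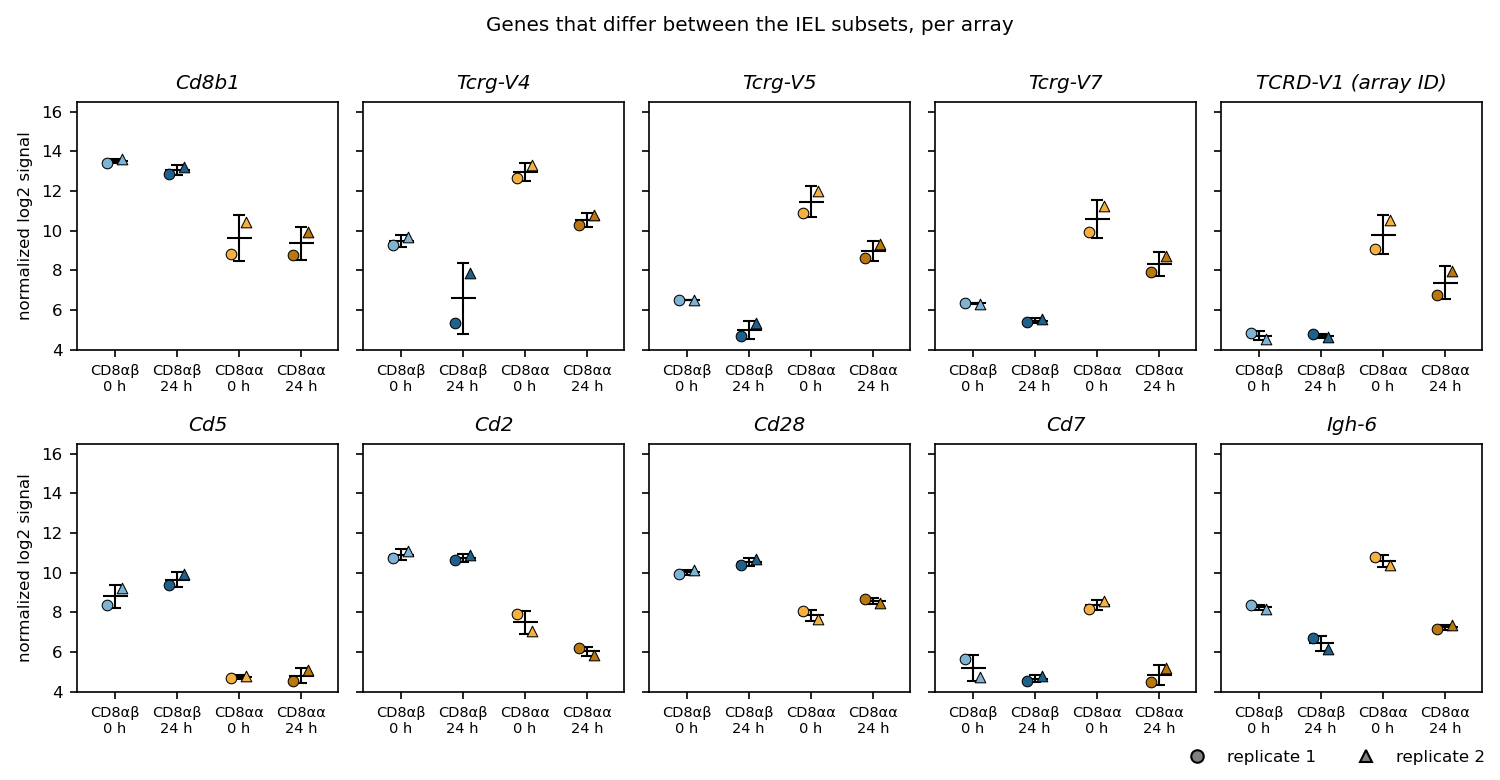
Normalized log2 signal of 10 genes or array IDs on each array, by subset and time; circles and triangles are replicates 1 and 2, the horizontal marks are group means and the bars are 1 SD (n = 2). Cd8b1 stands at 13.50 and 13.04 in CD8αβ IEL and below 11 on every CD8αα array, while Tcrg-V5 stands at 11.45 in CD8αα IEL and 6.50 in CD8αβ IEL at 0 h.

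The first comparison asked how CD8αβ IEL changed within 24 h of anti-CD3. Several cytokine and chemokine genes were among the largest rises, with 2 arrays in each group. Il3, a haematopoietic growth factor, rose at least 163-fold (log2 change 7.80, SE 0.81, adjusted p = 0.0113), Inhba, the βA subunit of activin, rose at least 53.3-fold (6.25, SE 0.62), and Csf2, which encodes GM-CSF, rose 37.7-fold (5.24, SE 1.04). The chemokines Ccl1 and Xcl1 rose 59.2-fold (5.89, SE 0.87) and 39.5-fold (5.30, SE 1.02). The retinoic acid binding protein gene Crabp2 rose at least 42.6-fold and Idi2, an isopentenyl diphosphate isomerase, at least 27.5-fold. The largest falls were those of Tspoap1 (at least 10.9-fold, log2 change −3.83, SE 0.74), Lcn4 (at least 6.58-fold), Osgin1 (at least 4.87-fold), the interferon-induced exonuclease gene Isg20 (at least 4.73-fold, −2.92, SE 0.49), Arap3 (5.95-fold) and Cmtm6 (5.79-fold). Ifng, the gene of interferon γ, did not pass (4.33, SE 1.20, adjusted p = 0.0842), its 0 h arrays standing at 9.01 and 13.37 and both 24 h arrays at 15.52. It passed with the replicate number as a block. Tnf (1.03, adjusted p = 0.128), Il2 (2.15, adjusted p = 0.286) and Cd69 (−1.13, adjusted p = 0.519) did not pass.

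Among genes downstream of the receptor, 9 of 23 tested rose in CD8αβ IEL and none fell (11 and 0 adjusted over the list alone). They included Rgs16 (4.23, SE 0.65), the orphan nuclear receptor Nr4a2 (3.76, SE 0.56), the costimulatory receptor Tnfrsf4 (3.20, SE 0.54) and the IL-2 receptor α chain Il2ra (2.65, SE 0.37). The median change of this list was 1.90 (camera adjusted p = 3.10e-07, adjusted p = 0.361 with an estimated correlation), and 1.01 with undetected members at their bound. Of 20 cytokine genes, 4 rose (7 adjusted over the list alone, with 1 lower), among them Il1a by at least 8.75-fold. Their median was 1.86 (adjusted p = 2.47e-05, adjusted p = 0.361 with an estimated correlation). Of 6 chemokines, 3 rose (5 adjusted over the list alone), although Ccl4 did not pass with the chip as a block (adjusted p = 0.0516). The median was 5.35 (adjusted p = 0.000995, adjusted p = 0.416 with an estimated correlation). Of 17 NF-κB genes, 6 rose (11 adjusted over the list alone), including Cd83 by at least 6.33-fold, Rel (2.87, SE 0.46) and Nfkb2 (2.22, SE 0.37). The median was 1.31 (adjusted p = 1.11e-07, adjusted p = 0.416 with an estimated correlation). Of 15 cytotoxic genes, Serpinb6b, a serine protease inhibitor, rose at least 20.6-fold and Crtam 13.7-fold, and the list itself did not pass (median 0.09, adjusted p = 0.540). The inhibitory receptor Lag3 rose 2.98-fold as 1 of 9 such genes (5 higher and 1 lower adjusted over the list alone), and the list did not pass (median 1.06, adjusted p = 0.124).

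Some genes of growth rose and others fell in CD8αβ IEL. All 29 ribosome assembly genes had positive changes, 3 of which passed (5 adjusted over the list alone), Rrp9 (1.64, SE 0.30), Pno1 (1.43, SE 0.19) and Rrp12 (1.32, SE 0.27). The median was 0.78 (adjusted p = 1.11e-07, adjusted p = 0.416 with an estimated correlation). Of 16 genes of protein folding in the endoplasmic reticulum, Hyou1 rose (1.76, SE 0.23; 4 genes adjusted over the list alone) and the median was 0.77 (adjusted p = 2.47e-05, adjusted p = 0.416 with an estimated correlation). Of 27 genes of amino acid supply, the glutamine transporter gene Slc1a5 rose (1.06, SE 0.22; none adjusted over the list alone). The median was 0.58 (adjusted p = 0.000334, adjusted p = 0.559 with an estimated correlation). All 20 mitosis genes had negative changes, of which Kif22 (−1.52, SE 0.28) and Spag5 (−1.37, SE 0.20) fell (11 genes adjusted over the list alone). The median was −1.11 (adjusted p = 1.11e-07, adjusted p = 0.416 with an estimated correlation). None of 32 S phase genes passed by either adjustment, and their median was −0.39 (adjusted p = 0.000510, adjusted p = 0.607 with an estimated correlation). Of 15 genes of gut homing and residence, Itgb7, the integrin β7 chain, fell 5.78-fold (−2.53, SE 0.46; 4 genes adjusted over the list alone). The median was −0.99 (adjusted p = 0.00230, adjusted p = 0.416 with an estimated correlation). Of 25 interferon-raised genes, Isg20 and Irf1 (−1.61, SE 0.31) fell (3 genes adjusted over the list alone). The median was −0.39 (adjusted p = 0.0114, adjusted p = 0.559 with an estimated correlation). Of 5 genes of epithelial repair tested, Pdgfa, a platelet-derived growth factor gene, rose from below detection (adjusted p = 0.0346; 2 genes adjusted over the list alone). The median was 1.99 (adjusted p = 0.0168, adjusted p = 0.416 with an estimated correlation) and 1.07 without 24 h replicate 1. Igh-6, the immunoglobulin μ heavy chain and a B cell marker, fell 3.56-fold (−1.83, SE 0.25) alongside these lists.

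In all, 318 of 7326 genes passed in CD8αβ IEL, 170 higher and 148 lower, and 1919 had an unadjusted p under 0.05. Both arrays of one time point lay beyond both of the other for 58.1% of genes, where chance would give 33.3% for exchangeable arrays, which those of the same replicate number were not. All 4 arrays of this comparison lay on chip 1; 493 genes passed with the chip as a block and 61 on chip 1 alone, which has fewer arrays to estimate the spread. The count was 18 without 0 h replicate 1, 43 without 0 h replicate 2, 22 without 24 h replicate 1, 115 without 24 h replicate 2 and 82 without either CD8αα 0 h array. Among named genes Il1a, Serpinb6b, Cd83 and Atf3 passed without any 1 array. A background estimated from all IDs gave 141 genes. Without 0 h replicate 1 the receptor list had a median of 1.00 and the chemokines 3.07. Without 24 h replicate 1 the cytokines had a median of 0.92, the gut homing list −0.57 and the interferon-raised list −0.24, while the amino acid list fell to 0.30 without 0 h replicate 2.

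**Figure D2:**
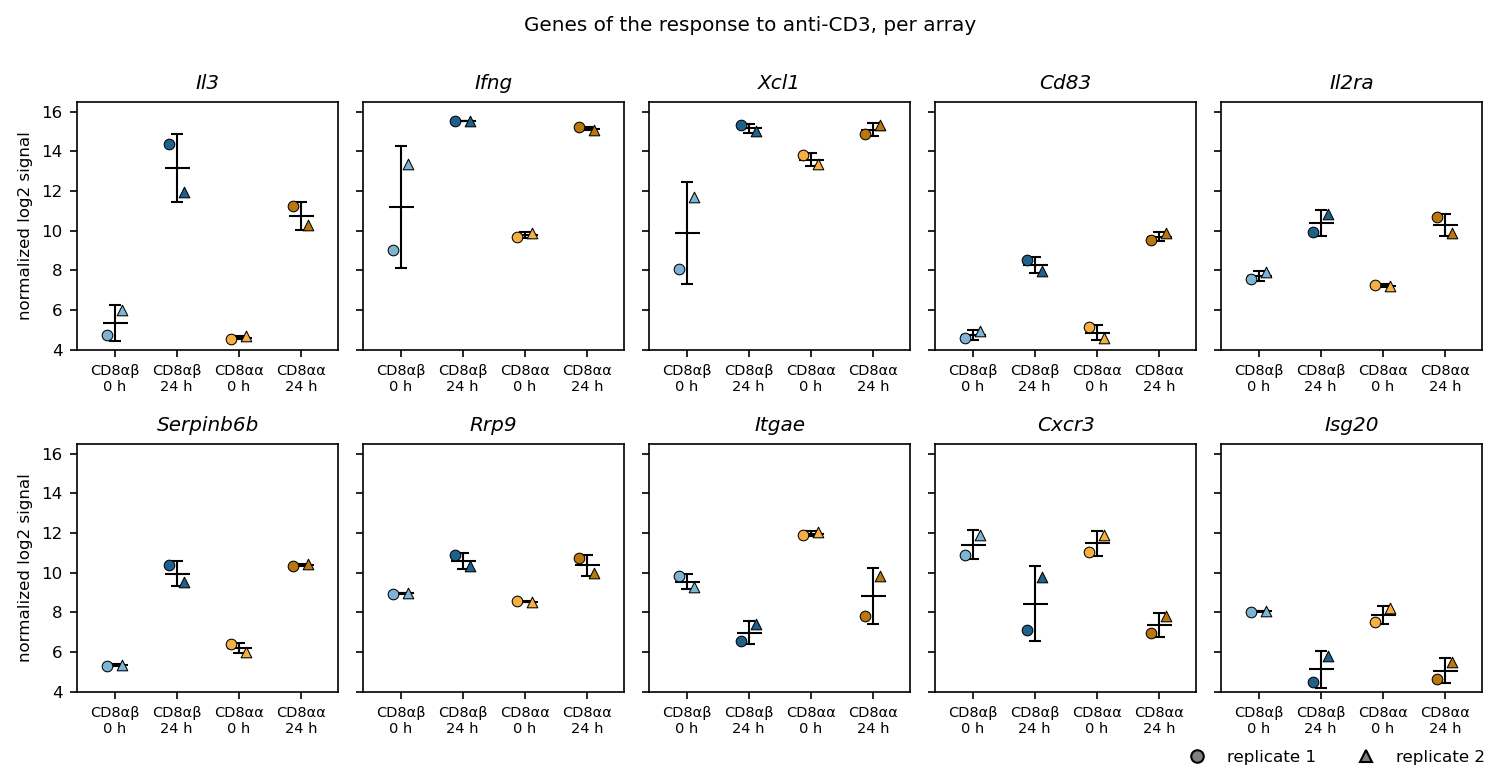
Normalized log2 signal of 10 genes of the response to anti-CD3 on each array, by subset and time; circles and triangles are replicates 1 and 2, the horizontal marks are group means and the bars are 1 SD (n = 2). Ifng stands at 9.01 and 13.37 in CD8αβ IEL at 0 h and at 15.52 on both arrays at 24 h, and Il3 stands at 4.72 and 6.00 on the CD8αβ arrays at 0 h.

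The second comparison asked the same of CD8αα IEL. Il3 rose at least 39.0-fold (log2 change 6.14, SE 0.81, adjusted p = 0.0161), Crabp2 at least 49.6-fold (6.01, SE 0.64), Idi2 at least 24.0-fold and Timd2, a TIM family surface protein gene, at least 16.3-fold, with 2 arrays in each group. Ifng rose 41.4-fold (5.37, SE 1.20, adjusted p = 0.0408) and Batf3, a transcription factor gene of the AP-1 family, 29.0-fold (4.86, SE 0.48). Falls were led by Ltb, which encodes lymphotoxin β (20.5-fold, −4.36, SE 1.02), Cxcr3, a chemokine receptor (17.1-fold, −4.10, SE 0.86), Pglyrp1 (−4.00, SE 0.60), Actn2 (15.4-fold), Smpdl3a (12.4-fold) and the surface protein gene Cd7 (at least 6.84-fold, −3.52, SE 0.37). Tnf did not pass (1.23, adjusted p = 0.0690), nor did Il2 (1.08, adjusted p = 0.549), Cd69 (−1.07, SE 1.02) or Tcrg-V4 (−2.43, adjusted p = 0.0811). Both Tnf and Tcrg-V4 passed with the replicate number as a block. The γ chain segment Tcrg-V7 fell 4.85-fold (−2.28, SE 0.46). It was the gene that passed among 8 receptor and CD8 genes (3 adjusted over the list alone), all with negative changes. The median was −0.87, −1.13 on chip 1 and −0.68 on chip 2 (adjusted p = 0.0120, adjusted p = 0.574 with an estimated correlation).

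Of the 23 genes downstream of the receptor, 12 rose in CD8αα IEL and none fell (12 higher and 1 lower adjusted over the list alone), including Rgs16 (3.48, SE 0.65), the transcription factor genes Irf4 (3.42, SE 0.28) and Irf8 (3.33, SE 0.52), and Il2ra (3.05, SE 0.37). Their median was 1.74, with 1.51 on chip 1 and 1.86 on chip 2 (adjusted p = 8.88e-06, adjusted p = 0.412 with an estimated correlation), and 1.21 with undetected members at their bound. Of 20 cytokine genes, 4 rose and Ltb fell (10 and 1 adjusted over the list alone). The median was 1.58, 1.76 on chip 1 and 1.37 on chip 2 (adjusted p = 0.000137, adjusted p = 0.412 with an estimated correlation); Tnfsf11, which encodes RANKL, rose 15.5-fold. The 6 chemokines had a median of 2.24, 1.19 on chip 1 and 3.41 on chip 2, and neither the list (adjusted p = 0.107) nor any member passed. Cd83 (at least 18.8-fold), Rel (2.31, SE 0.46) and Nfkb1 (1.48, SE 0.22) rose among 17 NF-κB genes (4 adjusted over the list alone). The median was 0.32, 0.21 on chip 1 and 0.70 on chip 2. The call of this list (adjusted p = 0.0120, adjusted p = 0.595 with an estimated correlation) was not made on chip 1 alone (adjusted p = 0.420), where the CD8αα response is 1 array against 1 and the spread comes from the CD8αβ groups. Serpinb6b rose 18.3-fold, Crtam rose 7.30-fold and the cathepsin gene Ctsw fell 7.46-fold among 15 cytotoxic genes, and the list did not pass (adjusted p = 0.596). Among 9 inhibitory receptors, Havcr2, which encodes TIM-3, rose 4.96-fold and Cd244a fell 3.06-fold (2 and 1 adjusted over the list alone; list adjusted p = 0.928).

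Of 29 ribosome assembly genes in CD8αα IEL, 12 passed, all higher (26 adjusted over the list alone), including Srm (2.27, SE 0.55), Nop2 (1.89, SE 0.39) and Rrp9 (1.83, SE 0.30). The median was 1.28, 1.32 on chip 1 and 1.16 on chip 2 (adjusted p = 4.15e-11, adjusted p = 0.470 with an estimated correlation). Of 27 genes of amino acid supply, Slc1a5 (1.11, SE 0.22) and the tRNA synthetase gene Iars (1.32, SE 0.28) rose (2 adjusted over the list alone). The median was 0.73, 0.84 on chip 1 and 0.67 on chip 2 (adjusted p = 0.000137, adjusted p = 0.574 with an estimated correlation). Hyou1 rose (1.32, SE 0.23; 1 gene adjusted over the list alone) in the folding list, whose median was 0.62, 0.37 on chip 1 and 0.79 on chip 2, and whose call (adjusted p = 0.00389, adjusted p = 0.574 with an estimated correlation) was not made on chip 1 alone (adjusted p = 0.0588, with the same limit). Of 11 heat shock and immediate early genes, which handling can also raise, 4 rose (5 adjusted over the list alone), among them Atf3 by at least 17.9-fold and the chaperone genes Hspd1 (1.67, SE 0.30) and Hspe1 (1.38, SE 0.20). The median was 0.96, 1.00 on chip 1 and 0.92 on chip 2 (adjusted p = 0.0133, adjusted p = 0.412 with an estimated correlation). Spag5 fell (−0.89, SE 0.20) as 1 of 20 mitosis genes (none adjusted over the list alone). The median was −0.58, −0.54 on chip 1 and −0.55 on chip 2 (adjusted p = 0.00786, adjusted p = 0.620 with an estimated correlation). The S phase list did not pass (median −0.01, 0.22 on chip 1 and −0.22 on chip 2; adjusted p = 0.792). Pdgfa rose 6.70-fold as 1 of 5 genes of epithelial repair (3 adjusted over the list alone). The median was 1.80, 1.48 on chip 1 and 1.35 on chip 2 (adjusted p = 0.0389, adjusted p = 0.448 with an estimated correlation).

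Some genes of residence and of the resting state fell in CD8αα IEL. Of 15 gut homing and residence genes, 5 fell (7 adjusted over the list alone), including Cxcr3, the integrin αE chain Itgae (−3.14, SE 0.63) and the purinergic receptor P2rx7 (at least 5.31-fold). The median was −1.66, −2.26 on chip 1 and −1.09 on chip 2 (adjusted p = 0.00896, adjusted p = 0.574 with an estimated correlation). Of 15 receptors and adaptors shared with natural killer cells, 6 fell (6 adjusted over the list alone), among them Cd7, Hcst (−2.80, SE 0.42) and Tyrobp (−2.14, SE 0.50), which encode adaptors of activating receptors. The median was −1.16, −1.37 on chip 1 and −0.79 on chip 2 (adjusted p = 0.00549, adjusted p = 0.448 with an estimated correlation). Of 21 genes of resting and memory T cells, 4 fell (7 adjusted over the list alone), including Ypel3 (−3.33, SE 0.78) and Pik3ip1 (at least 2.81-fold). The median was −0.90, −0.89 on chip 1 and −1.10 on chip 2 (adjusted p = 0.0201, adjusted p = 0.620 with an estimated correlation). Of 20 genes linked to conventional αβ T cells, 5 fell (8 lower and 2 higher adjusted over the list alone), including Gimap7 (−2.22, SE 0.27) and Bcl11b (−1.75, SE 0.42). The median was −0.81, −0.76 on chip 1 and −0.98 on chip 2 (adjusted p = 0.0389, adjusted p = 0.574 with an estimated correlation). Of 25 interferon-raised genes, 4 fell and Bst2 rose (6 and 1 adjusted over the list alone). The median was −0.52, −0.64 on chip 1 and −0.38 on chip 2 (adjusted p = 0.00409, adjusted p = 0.574 with an estimated correlation). Markers of other cells moved too. Igh-6 fell 10.1-fold (−3.33, SE 0.25), the epithelial cadherin Cdh1 at least 4.06-fold and H2-Eb1, a class II histocompatibility gene, at least 1.98-fold, while Lum, a fibroblast marker, rose at least 1.52-fold. The 6 myeloid markers tested, of which Tyrobp and H2-Eb1 fell (2 adjusted over the list alone), had a median of −1.02, −1.42 on chip 1 and −0.91 on chip 2 (adjusted p = 0.0333, adjusted p = 0.595 with an estimated correlation).

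In all, 814 genes passed in CD8αα IEL, 340 higher and 474 lower, and 2297 had an unadjusted p under 0.05. Both arrays of one time point lay beyond both of the other for 60.9% of genes, against 33.3% if arrays were exchangeable, which those of the same replicate number were not. With the chip as a block 1066 genes passed. Each of the 63 named genes that passed changed in the same direction on both chips. They were chosen on these same arrays, which largely fixed that outcome, so it is no independent replication. Chip 1 alone holds 1 pair of CD8αα arrays. On chips 1 and 2 Il3 rose by 6.69 and 5.59 and Crtam by 1.16 and 4.58, Ltb changed by −5.84 and −2.87 and Cxcr3 by −4.09 and −4.11. Crtam (adjusted p = 0.0522), Lum (0.0504) and Gimap6 of the conventional T cell list (0.0501) did not pass under the block. The count was 8 without 0 h replicate 2, 113 without 0 h replicate 1, 112 without 24 h replicate 1, 244 without 24 h replicate 2 and 365 without either CD8αβ 0 h array. Among named genes Timd2, Serpinb6b, Cd83 and Igh-6 passed without any 1 array. A background estimated from all IDs gave 370 genes. Among the lists that passed, medians that moved by over 1.5 times were that of mitosis, −0.20 without 24 h replicate 2 and −0.91 without 24 h replicate 1, of the heat shock list, 0.39 without 0 h replicate 1, of NF-κB, 0.84 without 24 h replicate 1, and of gut homing, −0.90 without 0 h replicate 2. Such fits set arrays of different chips against each other, and within chips 1 and 2 the mitosis median was −0.54 and −0.55. The resting list stood at −0.56 without 0 h replicate 2 and −1.61 without 0 h replicate 1, the interferon-raised list at −0.32 without 24 h replicate 1 and −0.88 without 24 h replicate 2, and the myeloid markers at −0.67 without 0 h replicate 1 and −1.60 without 0 h replicate 2.

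**Figure D3:**
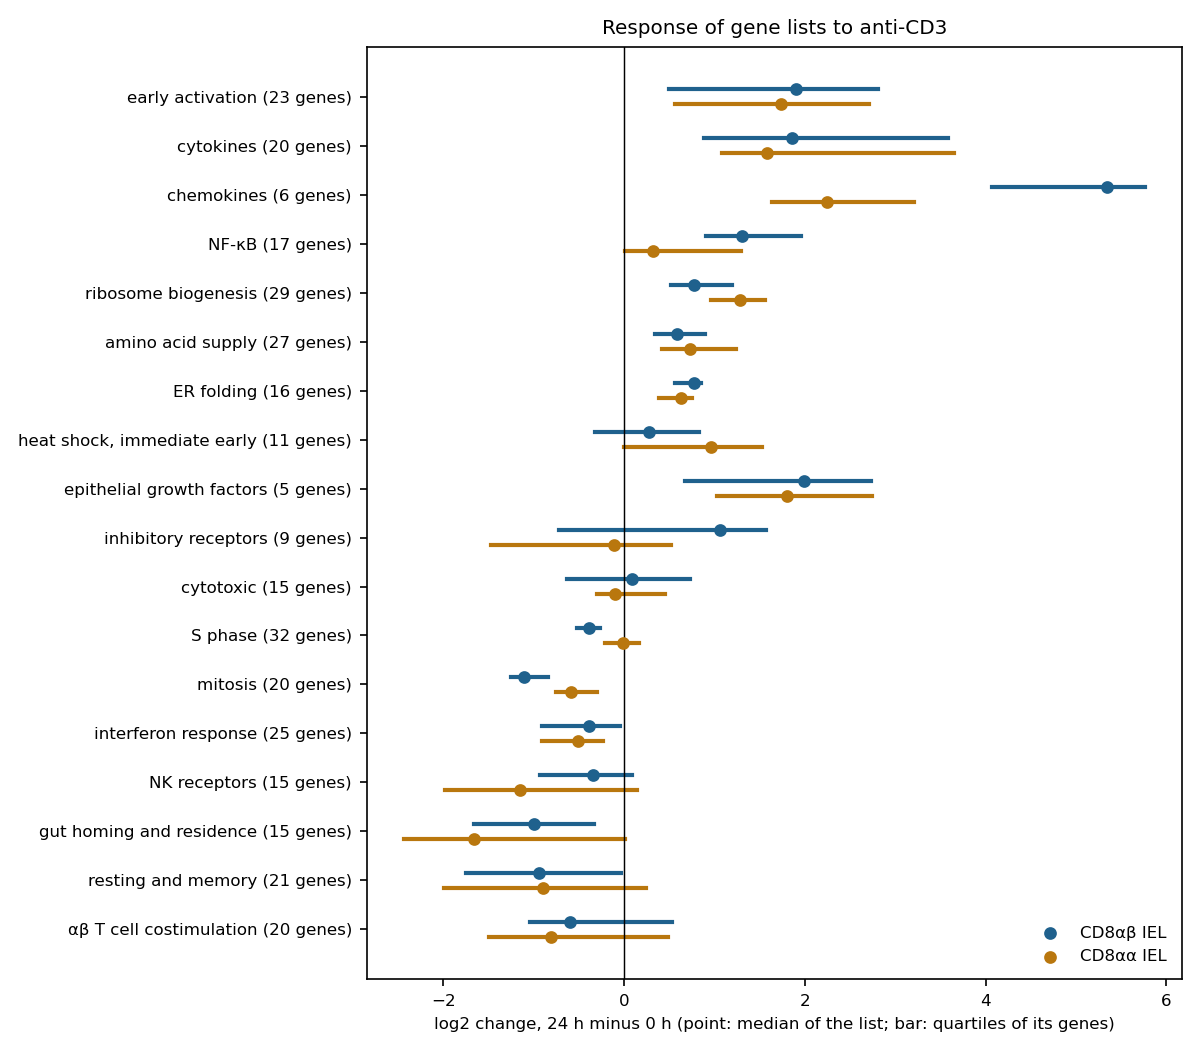
Median log2 change from 0 h to 24 h of 18 gene lists (points) with the quartiles of their genes (bars), for CD8αβ IEL and CD8αα IEL. Chemokines stand at 5.35 in CD8αβ IEL and 2.24 in CD8αα IEL, and ribosome assembly genes at 0.78 and 1.28.

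The third comparison set both responses side by side. They shared 250 genes, 131 that rose and 119 that fell in both subsets, against 7.89 and 9.58 shared by independent lists of those lengths, and 0 genes passed with opposite signs. Il3, Crabp2, Idi2, Cd83, Serpinb6b, Rel, Il2ra, Atf3, Rrp9 and Hyou1 passed in both as rises, and Isg20, Irf1, Igh-6, Gimap7 and Rasa3 as falls. Of 882 genes that passed in either subset, 875 changed in the same direction. Across all 7326 genes the 2 log2 changes correlated with r = 0.879 (Spearman's rho 0.875); genes are not independent replicates, and the responses share no 0 h array. The shared count was 0 on chip 1 alone, where no gene passed in CD8αα IEL, and 104 with a background estimated from all IDs. The difference of the responses itself passed for 0 genes by limma (smallest adjusted p 0.632), with 132 genes at an unadjusted p under 0.05, and 1 gene passed with a background estimated from all IDs, Inhba. Thus a gene past the test in one subset and not in the other, such as Ifng, is not shown to differ between them. Of 28 lists, 10 passed by camera for this difference and 0 with an estimated correlation; they are taken up in the closing section.

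**Figure D4:**
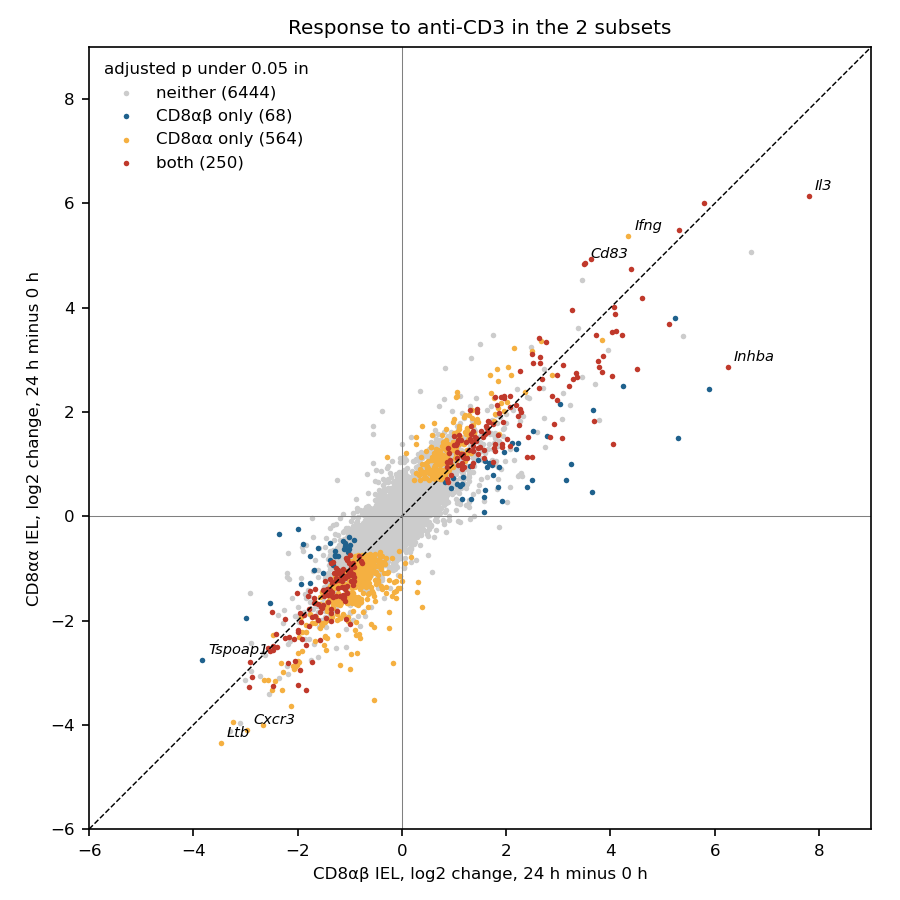
Log2 change from 0 h to 24 h of each of 7326 genes in CD8αβ IEL (x axis) and CD8αα IEL (y axis), coloured by the subset in which the adjusted p was under 0.05; the dashed line marks equal change. The 250 genes that passed in both lie in the upper right and lower left of the plot.

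The fourth comparison set the subsets against each other before restimulation. Of the γ receptor chain segments, 2 were higher in CD8αα IEL: Tcrg-V5 by 30.9-fold (log2 difference 4.95, SE 0.43, adjusted p = 0.0197; 4.49 with the chip as a block and 4.39 on chip 1) and Tcrg-V7 by 19.1-fold (4.26, SE 0.46; 3.71 and 3.59), with 2 arrays in each group. Also higher were the transcriptional coactivator gene Cited4 (at least 6.82-fold; 3.21 and 3.59), Chn2, a Rac-directed GTPase-activating protein gene (11.0-fold; 3.48 and 3.57), Cd7 (at least 6.83-fold; 2.92 and 3.00) and the adaptor gene Grb7 (6.04-fold; 2.45 and 2.53). Lower were Cd5 by at least 10.1-fold (−4.07, SE 0.35; −4.24 and −4.14), Cd2, a receptor for CD48, by 10.7-fold (−3.41, SE 0.32; −3.12 and −3.00) and the costimulatory receptor Cd28 by 4.45-fold (−2.15, SE 0.22; −2.01 and −1.96). Ms4a6d, Tmem51, Tmie and the AP-1 family gene Fosl2 (3.06-fold) were lower too. Cd8b1 did not pass (−3.89, SE 0.58, adjusted p = 0.0792), but passed with the chip as a block (−4.59, SE 0.24, adjusted p = 0.00995), and Tcrg-V4 did not (3.48, SE 0.75, adjusted p = 0.226). Both Cd8b1 and Tcrg-V4 passed with the replicate number as a block. The B cell marker Igh-6 was 4.98-fold higher in CD8αα IEL (2.32, SE 0.25; 2.37 and 2.53).

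By lists, Cd5, Cd2 and Cd28 were lower among 20 genes linked to conventional αβ T cells (4 lower and 1 higher adjusted over the list alone). The median was −0.31, −0.44 with the block and −0.60 on chip 1 (adjusted p = 0.0208, adjusted p = 0.525 with an estimated correlation). Cd7 was higher among 15 genes shared with natural killer cells (5 higher and 2 lower adjusted over the list alone). The median was 0.82, 1.04 with the block and 1.09 on chip 1 (adjusted p = 0.000891, adjusted p = 0.525 with an estimated correlation). No member passed in the lists that follow. The chemokines had a median of 1.73, 1.95 with the block and 2.29 on chip 1 (2 genes adjusted over the list alone; adjusted p = 0.000947, adjusted p = 0.525 with an estimated correlation), and 0.48 without CD8αβ replicate 1. The NF-κB genes had a median of 0.61, 0.54 with the block and 0.76 on chip 1 (2 genes adjusted over the list alone; adjusted p = 1.36e-05, adjusted p = 0.525 with an estimated correlation). The inhibitory receptors had one of 0.94, 0.77 with the block and 0.92 on chip 1 (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.00477, adjusted p = 0.525 with an estimated correlation). The median of the ribosome assembly genes was −0.43, −0.22 with the block and −0.25 on chip 1 (none adjusted over the list alone; adjusted p = 2.78e-06, adjusted p = 0.525 with an estimated correlation). That of the mitosis genes was −0.50, −0.19 with the block and −0.21 on chip 1 (none adjusted over the list alone; adjusted p = 5.34e-05, adjusted p = 0.525 with an estimated correlation). The genes of amino acid supply stood at −0.42, −0.35 with the block and −0.37 on chip 1 (none adjusted over the list alone; adjusted p = 9.57e-06, adjusted p = 0.525 with an estimated correlation), but −0.15 without CD8αβ replicate 1. The 15 glycolysis genes, all with negative differences, stood at −0.42, −0.26 with the block and −0.20 on chip 1 (none adjusted over the list alone; adjusted p = 0.000891, adjusted p = 0.525 with an estimated correlation), but −0.11 without CD8αβ replicate 1. The S phase genes stood at −0.25, −0.07 with the block and −0.21 on chip 1 (adjusted p = 0.000929, adjusted p = 0.593 with an estimated correlation; adjusted p = 0.0961 with the block). Sterol synthesis genes stood at −0.30, −0.05 with the block and −0.03 on chip 1 (adjusted p = 0.0148, adjusted p = 0.638 with an estimated correlation; adjusted p = 0.403 with the block), and at 0.04 without CD8αβ replicate 1. The heat shock list stood at −0.22, −0.23 with the block and −0.13 on chip 1 (adjusted p = 0.0258, adjusted p = 0.525 with an estimated correlation). The apoptosis genes stood at 0.10, 0.03 with the block and 0.01 on chip 1 (adjusted p = 0.0448, adjusted p = 0.525 with an estimated correlation; adjusted p = 0.494 with the block). No member of these 4 lists passed by either adjustment. The myeloid markers had a median of 1.26, 1.66 with the block and 1.70 on chip 1 (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.0258, adjusted p = 0.525 with an estimated correlation).

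Between the subsets at 0 h, 21 genes passed, 13 higher and 8 lower in CD8αα IEL, and 509 had an unadjusted p under 0.05; the submitters' own normalized values gave 11 genes, 8 of them higher. Both arrays of one subset lay beyond both of the other for 39.0% of genes, against 33.3% if arrays were exchangeable, which those of the same replicate number were not. With the chip as a block 9 genes passed, 6 of them among the 21. All 14 named genes that passed kept their direction on chip 1 alone, whose arrays were among those used to choose them. Under the block Tcrg-V5, Tcrg-V7, Chn2, Grb7, Cd5 and Cd2 passed, and Cited4, Cd7, Igh-6, Ms4a6d, Tmem51, Tmie, Cd28 and Fosl2 did not. The count was 0 without CD8αα replicate 2, 0 without either CD8αβ 24 h array, 1 without CD8αβ replicate 2, 3 without CD8αα replicate 1, 10 without CD8αβ replicate 1, 6 without either CD8αα 24 h array and 0 with a background estimated from all IDs. Without CD8αα replicate 1 the conventional T cell list stood at −0.12 and the natural killer list at 0.45. Without CD8αα replicate 2 mitosis stood at −0.21, ribosome assembly at −0.25, the heat shock list at −0.13 and apoptosis at 0.01. Without CD8αβ replicate 2 NF-κB stood at 0.95 and the myeloid markers at 0.72.

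The last comparison set the subsets against each other at 24 h. Tcrg-V5 was at least 9.57-fold higher in CD8αα IEL (log2 difference 3.98, SE 0.43, adjusted p = 0.0317; 3.53 with the chip as a block and 3.62 on chip 1), Chn2 at least 4.72-fold (3.13 and 3.05), Grb7 at least 3.24-fold (2.16 and 2.08). So was Ckm, the muscle creatine kinase gene, at least 1.72-fold (1.91 and 1.82), with 2 arrays in each group. Lower were Cd5, not detected in CD8αα IEL (adjusted p = 0.0120), Cd2 by 26.4-fold (−4.72, SE 0.32; −4.43 and −4.55), Sh2d1a, the adaptor of SLAM family receptors, by at least 17.7-fold (−4.35, SE 0.50; −3.81 and −3.94). Also lower were Akr1b8 by at least 5.58-fold (−2.82 and −2.72), Fam169b by 4.42-fold (−2.18 and −2.06) and Cd28 by 3.90-fold (−1.96, SE 0.22; −1.82 and −1.87). The cytokine gene Il1a was 6.96-fold lower (−2.80, SE 0.34, adjusted p = 0.0446; −2.68 and −2.56). Neither Il1a nor Cd28 passed with the block. Cd8b1 did not pass (−3.68, SE 0.58, adjusted p = 0.141) but passed with the chip as a block (−4.38, SE 0.24, adjusted p = 0.0113), as did Tcrg-V7 (2.86, SE 0.46, adjusted p = 0.152; 2.31, SE 0.22, adjusted p = 0.0420 under the block). Tcrg-V4 passed in neither (3.95, SE 0.75, adjusted p = 0.260). With the replicate number as a block Cd8b1, Tcrg-V7 and Tcrg-V4 all passed.

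Cd5, Cd2 and Cd28 were again the genes that passed among 20 genes linked to conventional αβ T cells (5 lower adjusted over the list alone), whose median at 24 h was −0.53, −0.62 with the block and −0.74 on chip 1 (adjusted p = 1.81e-07, adjusted p = 0.559 with an estimated correlation), and −0.16 without CD8αα replicate 1. No member passed, by either adjustment, among genes of amino acid supply (median −0.23, −0.16 with the block and −0.09 on chip 1; adjusted p = 0.000154, adjusted p = 0.881 with an estimated correlation). None passed in sterol synthesis either (−0.38, −0.11 with the block and −0.18 on chip 1; adjusted p = 0.000239, adjusted p = 0.881 with an estimated correlation), or in oxidative phosphorylation (0.13, 0.12 with the block and 0.12 on chip 1; adjusted p = 0.00106, adjusted p = 0.773 with an estimated correlation). Without CD8αβ 24 h replicate 1 the amino acid list stood at −0.07, and without CD8αα 24 h replicate 2 the sterol list at −0.18. On chip 1 alone these lists did not pass (adjusted p = 0.147, 0.140 and 0.0754), and with the chip as a block neither the sterol nor the oxidative phosphorylation list passed. At 24 h 16 genes passed, 4 higher and 12 lower in CD8αα IEL, and 277 had an unadjusted p under 0.05; the submitters' own normalized values gave 6 genes, all lower. Both arrays of one subset lay beyond both of the other for 22.7% of genes. The 33.3% of exchangeable arrays is no fair reference here, since arrays of the same replicate number deviated alike. With the chip as a block 13 genes passed, and on chip 1 alone 0. The count was 0 without CD8αα 24 h replicate 1 or CD8αβ 24 h replicate 1, 1 without replicate 2 of either, 8 without either CD8αα 0 h array, 10 without either CD8αβ 0 h array and 1 with a background estimated from all IDs.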

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

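The difference of the responses was among the tests planned, and the tests of explanations below were all chosen after the results were seen. Lists drew attention where the response of CD8αα IEL differed from that of CD8αβ IEL by camera in limma, whose calls all ended with an estimated correlation. The 32 S phase genes all had a positive difference (median 0.37, 0.59 on chip 1; adjusted p = 3.04e-07, adjusted p = 0.587 with an estimated correlation), as had 19 of 20 mitosis genes (0.55, 0.60 on chip 1; adjusted p = 1.70e-06, adjusted p = 0.587 with an estimated correlation). All 29 ribosome assembly genes had one too (0.41, 0.49 on chip 1, 0.11 without CD8αα 24 h replicate 1; adjusted p = 1.29e-05, adjusted p = 0.603 with an estimated correlation). The NF-κB genes had a negative one (−0.73, −1.03 on chip 1, −0.29 without CD8αα 24 h replicate 1; adjusted p = 6.42e-05, adjusted p = 0.587 with an estimated correlation). So had all 6 chemokines (−1.79, −2.80 on chip 1, −0.41 without CD8αβ 0 h replicate 1, adjusted p = 0.000205, adjusted p = 0.564 with an estimated correlation). At 24 h Ccl3 (15.80 to 15.85), Ccl4 (15.22 to 15.61) and Xcl1 (14.86 to 15.32) stood near the top of the arrays in both subsets, while Ccl9 was lower in CD8αα IEL. At 0 h the chemokine median had been 1.73 higher in CD8αα IEL (0.48 without CD8αβ replicate 1), so their difference may reflect 0 h levels and a ceiling at 24 h. The natural killer list stood at −0.32 (−0.89 on chip 1, −0.15 without CD8αα 0 h replicate 1; adjusted p = 0.000217, adjusted p = 0.473 with an estimated correlation). The conventional T cell list stood at −0.44 (−0.36 on chip 1, −0.13 without CD8αβ 24 h replicate 2; adjusted p = 0.00744, adjusted p = 0.564 with an estimated correlation). The inhibitory receptors stood at −0.80 (−0.95 on chip 1, −0.00353 without CD8αα 24 h replicate 1; adjusted p = 0.0146, adjusted p = 0.473 with an estimated correlation). Oxidative phosphorylation stood at 0.11 (0.12 on chip 1, where adjusted p = 0.0780; 0.19 without CD8αβ 24 h replicate 1; adjusted p = 0.0170, adjusted p = 0.564 with an estimated correlation). The heat shock list stood at 0.33 (0.22 on chip 1, where adjusted p = 0.102; 0.12 without CD8αβ 0 h replicate 2; adjusted p = 0.0236, adjusted p = 0.473 with an estimated correlation).

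The chemokine difference was −4.27 without CD8αβ 0 h replicate 2 and −0.41 without replicate 1, and the explanations tested here concern the gap between these arrays, which made the difference smaller: replicate 2 was higher than replicate 1 in Ifng (13.37 and 9.01), Ccl3 (13.20 and 7.72) and Xcl1 (11.68 and 8.04). RNA of the 24 h culture mixed into that sample would raise all genes of the response by a similar share of their 24 h signal. Over 53 genes raised at least 4-fold in CD8αα IEL the median share was 2.35% (quartiles 0.361 and 5.56%), against 21.6% for Ifng. Ifng stood at 15.52 on both CD8αβ 24 h arrays, near the top of the arrays, and a ceiling there would inflate its share. The chemokines were left out of the 53 genes and their shares were not compared, so mixing is not decided for them. As for a shift between replicate numbers common to both subsets, it would raise the chemokines in CD8αα IEL too, but their median difference there was −1.10, against 3.03 in CD8αβ IEL; its upper quartile was −0.592, a bound set in place of the maximum after Ccl5 alone was seen to be positive (0.130). Across all tested genes, however, the replicate differences of both subsets at 0 h correlated with r = 0.664, so a shared shift was present. Egr1 (by 4.80 and 2.37), Fos (5.62 and 3.26) and Cd69 (2.59 and 1.84), for example, were higher in replicate 2 of both CD8αβ and CD8αα IEL at 0 h. Engagement of the receptor in that culture before restimulation stays open and was not tested.

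The differences of the responses of the mitosis and S phase lists were mostly positive, although no single gene passed and both calls ended with an estimated correlation (adjusted p = 0.587). The array with the fewest detected IDs, CD8αβ 24 h replicate 1, does not account for the S phase median, which was 0.400 without it. Nor do the chips: an added chip effect cancels from this difference, and on chip 1 alone the S phase median was 0.594 with 32 of 32 genes positive, a value that rests on 1 pair of CD8αα arrays. Without CD8αα 24 h replicate 1 the S phase median was 0.0846, with 19 of 32 genes positive. That fit sets a chip 2 array at 24 h against 0 h arrays of both chips, so a chip or replicate shift no longer cancels. Matched by replicate number, the S phase medians for replicate 1 were 0.22 in CD8αα and −0.39 in CD8αβ IEL. For replicate 2 they were −0.22 and −0.45. For mitosis the median was 0.128 without that array and 0.217 without CD8αα 0 h replicate 2, each with 17 of 20 genes positive. Its matched medians were −0.54 and −1.36 for replicate 1, and −0.55 and −0.80 for replicate 2. For both lists a single array and a difference of the subsets cannot be told apart, and the latter stays open and untested.

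Of the B and myeloid cell markers, Igh-6 passed as higher in CD8αα IEL at 0 h (2.32, adjusted p = 0.0312), while among markers that did not pass the means of Fcer1g (13.24 against 8.10 in CD8αβ IEL), Tyrobp (7.98 against 4.73), Cd79b (9.21 against 6.57) and H2-Eb1 (6.58 against 4.94) were higher and those of Cd14 (5.06 against 6.12) and Cd68 (6.12 against 6.86) lower. B cells would bring all their abundant transcripts, but the highest mean of Cd79a, Ms4a1, IgK and Jchain was 5.09, under the lowest levels detected on those arrays (5.38 and 5.55), with Igh-6 itself at 10.58 and Cd79b at 9.21. That argues against B cells only as far as those IDs work, which no B cell sample here shows. The ID of Cd8a was undetected on every array of these CD8 cells too, so B cells stay open. For Lyz2, C1qa, C1qb, C1qc, Csf1r, S100a8 and S100a9 the highest mean was 4.59, Itgax, Flt3, Itgam and Adgre1 were undetected too, and the cells had been cultured for 14 days and sorted, which argues against myeloid cells, but Cd74 (7.32) and H2-Ab1 (8.28) were detected, which leaves a small share of them open. Expression of these genes by the IEL themselves may be the source of Igh-6 and was not tested.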

How the results depend on the processing

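Most alternatives here were planned. The background from all IDs was the version run first, and the single-probe background of the main results was chosen after its results were seen. Detection read from signals was also added after the data were seen. Over 26 settings, none of the named genes that passed changed sign, though they had been chosen for passing on these same arrays. The median of all genes moved by at most 0.09 under any scaling. Among genes that did not pass, Cd69 in CD8αβ IEL ranged from −2.43 without CD8αβ 0 h replicate 1 to 0.17 without CD8αβ 0 h replicate 2. Il2 in CD8αα IEL was −0.16 without CD8αα 0 h replicate 1 and −0.12 without CD8αα 24 h replicate 2, and ranged up to 2.33 without CD8αα 0 h replicate 2.

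In the CD8αβ response (318 genes) 171 passed with no filter, 205 among genes detected on all 8 arrays, 493 with the chip as a block, 61 on chip 1 alone, 61 with only the arrays of the 2 groups, 480 with array weights and 141 with the background from all IDs. In the CD8αα response (814) the counts were 482 with no filter, 0 on chip 1 alone, 65 with only the 2 groups and 370 with the background from all IDs. Between the subsets at 0 h (21), 11 passed with no background correction, 13 with median scaling, 11 with the submitters' values, 2 with no filter, 0 among genes detected on all 8 arrays, 9 with the chip block, 0 on chip 1 alone, 2 with only the 2 groups, 46 in probes and 0 with the background from all IDs. Between them at 24 h (16), the counts were 9 with no background correction, 9 with median scaling, 6 with the submitters' values, 2 with no filter, 2 among genes detected on all 8 arrays, 0 on chip 1 alone, 5 with only the 2 groups, 8 with array weights, 30 in probes and 1 with the background from all IDs. For the difference of the responses (0 genes by limma, 132 at an unadjusted p under 0.05) that background gave 1 gene. The genes shared by both responses (250) numbered 0 on chip 1 alone and 104 with that background.

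With each array left out in turn, the counts ranged from 18 to 237 in the CD8αβ response, 8 to 574 in the CD8αα response, 0 to 10 between the subsets at 0 h and 0 to 10 at 24 h, and stayed at 0 for the difference of the responses. The labels tie the samples only by a replicate number. Their values nonetheless shared a shift: deviations from the group means correlated between arrays of the same number with r from 0.493 to 0.664 over all 6 pairs of groups. The main model leaves this shift in the spread. With the number as a block 2001, 2640, 115, 41 and 0 genes passed in the 5 comparisons. Of the named genes that had not passed, only some were read with this block, and the CD3 chains were not among them. Of those read, Ifng passed in the CD8αβ response, and Tnf and Tcrg-V4 in the CD8αα response. Between the subsets, Cd8b1 and Tcrg-V4 passed at both times, and Tcrg-V7 at 24 h. The cause of the shared shift was not tested.

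For the gene lists, 0 passed with an estimated correlation in any of the 5 comparisons, and fry gave 5, 6, 1, 0 and 0, against 12, 16, 14, 4 and 10 by camera. Of the lists that passed in the CD8αα response, 3 did not with the submitters' values and 3 did not with the background from all IDs. Some medians shrank on other scales: that of the receptor list in CD8αβ IEL (1.90) was 0.93 with no background correction and 0.77 with the submitters' values, and that of epithelial repair (1.99) was 0.83 with the latter. Others grew, as that of the chemokines in CD8αβ IEL from 5.35 to 5.62 with median scaling. The median of oxidative phosphorylation in CD8αβ IEL, a list that had not passed, changed sign with that scaling, from −0.09 to 0.02. With the chip block 8 lists passed between the subsets at 24 h.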

Other observations

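The test of these lists was planned. Several programmes did not pass as lists in either response, although single members did. Genes of cytosolic ribosomal proteins, 36 of them, had medians of 0.02 in CD8αβ IEL (adjusted p = 0.955) and −0.08 in CD8αα IEL (adjusted p = 0.360) with no member past the test. Glycolysis (0.04 and 0.37; adjusted p = 0.792 and 0.210), oxidative phosphorylation (−0.09 and 0.07; adjusted p = 0.660 and 0.360) and sterol synthesis (0.23 and 0.19; adjusted p = 0.188 and 0.440) had no member that passed either. Among feedback regulators of receptor signalling, Socs3 rose in CD8αβ IEL (2.27, SE 0.37) and in CD8αα IEL (2.06, SE 0.37), and the list did not pass (adjusted p = 0.242 and 0.493). Of 24 apoptosis genes, the survival gene Bcl2l1 rose in both (1.59, SE 0.25, and 1.57, SE 0.25), Casp4 rose in CD8αβ IEL (1.73, SE 0.27) and Casp1 fell in CD8αα IEL (−1.13), and the list did not pass (adjusted p = 0.949 and 0.634).

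Of 19 cytokine receptors, Ifngr1 fell in CD8αβ IEL (−1.80, SE 0.23) and in CD8αα IEL (−1.53), where Ifnar2 (−1.33) and Tgfbr2 (−1.47) also fell and Il10ra rose (1.39, SE 0.24), and the list did not pass (adjusted p = 0.218 and 0.243). In CD8αβ IEL the resting list (−0.94, adjusted p = 0.0699), of which Rasa3 fell (−1.68, SE 0.31), the receptor and CD8 genes (−0.61, adjusted p = 0.0778), the natural killer list (−0.34, adjusted p = 0.185), the conventional T cell list (−0.60, adjusted p = 0.373), the myeloid markers (−0.54, adjusted p = 0.177) and the heat shock list (0.27, adjusted p = 0.0901) did not pass. The first pair passed with the chip as a block (adjusted p = 0.0414 and 0.0249). Innate γδ lineage genes passed in neither subset (adjusted p = 0.295 and 0.172), with a median of −0.73 in CD8αβ IEL. None of 14 type I and III interferon genes and none of 13 mast cell markers on the array was tested. Detected on no array were 11 of the 13 mast cell, 23 of 26 epithelial, 18 of 26 myeloid and 14 of 16 stromal and erythroid markers. Of the mast cell markers, Kit was detected on 5 arrays, with means of 8.02 in CD8αα and 5.23 in CD8αβ IEL at 0 h, and Cpa3 on 1.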
